A study of Mus musculus with 2 samples.

How the data were processed

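Chromatin from aortic endothelial cells of wild-type mice was immunoprecipitated with an antibody against ETS1 or an antibody against ETS2, both members of the ETS family of transcription factors, and sequenced as single-end reads (ChIP-seq). Per the labels' protocols, 10 µg of antibody was used for each immunoprecipitation, and the cells had been grown with 20% fetal bovine serum, heparin and endothelial growth supplement at 5% CO2. The samples form 2 groups of 1 library each, named by the antibody in the sample title. An input or IgG library was not analysed here, and there are no replicates, so every test below describes these peak lists and not the factors.

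Per the submitters' processing notes, CASAVA 1.8, Bowtie2 and HOMER were used, and the genome builds mm9 and mm10 are both named. Per the file headers, the peaks were called with HOMER findPeaks in its factor style from tag directories named for mm10, so the coordinates were read as mm10. The deposited file headers give no control directory in the calling command, and the options for fold over control, fold over local signal and Poisson significance against control were set to 0. Per the file headers the false discovery rate was 0.01 and the threshold was 30 tags in a peak for both libraries, beside 12.7 tags expected by chance per peak for ETS1 and 12.5 for ETS2. With these settings 0 peaks were removed by the local-signal filter and 0 by the clonal filter, per the file headers. One threshold therefore applied to the whole genome, and a chromosome or segment with more reads passes it more often. Each deposited peak has a fixed width, 177 bp for ETS1 and 187 bp for ETS2, and 1 peak in each list has another width. The score column deposited by the authors holds the constant 1 in every row and the strand column holds a single value, so neither was used to rank peaks.

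The headers give 143778022 total tags for ETS1 and 134607908 for ETS2, with 2710479 tags (1.89%) and 2059428 tags (1.53%) inside peaks. Tag counts of single peaks were not used here. Intervals are 95% Wilson intervals for shares and 95% intervals of odds ratios. They cover counting error only, because neighbouring peaks and peaks of one library are not independent.

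Gene positions came from a RefSeq gene table of GRCm38.p6, whose primary chromosomes are those of mm10, with 21887 protein-coding genes. The table gives the first and last base of each gene but no strand, exons or sequence. The design called for promoters within 1 kb of a transcription start, for UTR and exon classes, for DNA motifs and for promoter CpG matching. These need strand, exons or sequence. In place of a promoter, the window within 1 kb of either annotated gene end was used, so a peak counted there can lie at the start or at the finish of transcription. The motif tests, the UTR and exon classes, the CpG-matched backgrounds and the comparison of builds by shifted peaks were not run. Peaks on chromosomes 1 to 19, X and Y entered the comparisons, except that the shares along the deposited order and the leading peaks were taken over all deposited peaks, mitochondrial and unplaced ones included. Coordinates are 1-based.

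Overlap was counted as at least 1 bp between an ETS1 and an ETS2 peak and set against 1000 random placements of the ETS2 peaks on the same chromosomes with widths kept, where the smallest possible p is 0.001. Alternatives with 100 placements cannot go below 0.01. Peak centres were assigned to gene end (within 1 kb), gene body or intergenic in that order, beside 1000000 random positions spread over the chromosomes as the peaks were. Peaks shared by both lists were compared with the other peaks of the same list by Fisher's exact test. The 17 gene lists fixed before the data were examined held 492 entries, and 492 matched a symbol. They were tested against all other protein-coding genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 34 tests. The background includes genes silent in endothelial cells, because no expression data were used here. Peaks within a gene and 10 kb around it were counted per gene and set against 10000 random lists of protein-coding genes matched on length in 20 bins (permutation test, two-sided, adjusted over 34 tests).

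Genes named in the text follow a rule set before the data were examined. It takes Ets1 and Ets2, up to 3 genes of each list with a peak at an end in both peak lists, up to 2 in the ETS1 list only, up to 2 in the ETS2 list only and up to 2 in neither. It also takes the genes nearest the leading peaks of each list, and the 5 genes with most peaks per locus. The rule ranks genes by peak score or width. As neither varies, the order of genes within each fixed list was used, and the deposited peak order replaced the score for the leading peaks. Other genes named were chosen after their values were seen. Some genes that the rule takes are not reported here. The alternatives changed the overlap definition, the random placement, the distance windows, the peaks used and the gene background.

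Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and list steps were tested on simulated data first. With 20% of 63343 simulated ETS2 peaks planted on ETS1 peaks, 21.0% were found shared, beside 1.32% with none planted. Among 200 simulated lists of 40 genes drawn at random from 21887 genes, 5% had p under 0.05, and 97% of 200 lists of 40 genes with a peak at 70% of members, against 40% of all genes, did. This simulation gave every gene the same independent chance of a peak. It therefore does not show how the list test behaves where that chance varies by chromosome or gene length, as in these lists.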

Results

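Peaks of an ETS1 and an ETS2 antibody were mapped by ChIP-seq in cultured mouse aortic endothelial cells. With no input library analysed and no motif test, they are not shown to be binding sites of either factor. Peaks held 2.76 (ETS1) and 2.57 (ETS2) times the share of tags that their share of genome length would give. At 1.5 times the expected tags, a Poisson count would reach 30 tags in 1.25% (ETS1) and 1.02% (ETS2) of windows. ETS1 and ETS2 are closely related transcription factors that recognise a GGAA core and act downstream of RAS-ERK signalling. The deposited list held 77295 peaks for the ETS1 antibody and 63556 for the ETS2 antibody, from 143778022 and 134607908 tags. There was 1 library per antibody, so values below carry counting error only and no difference between the antibodies could be set against a spread between replicates. All coordinates are mm10.

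Peaks were spread unevenly over the chromosomes, and unevenly in a different way in each list. The ETS1 list had a median of 35.3 peaks per Mb over the 19 autosomes but 6.44 on chromosome 4, 7.57 on chromosome 5, 7.91 on chromosome 7 and 8.55 on chromosome 19. The ETS2 list had a median of 19.6 peaks per Mb, with 103.9 on chromosome 6 and 56.0 on chromosome 10. Chromosome 6 alone held 15524 ETS2 peaks, 24.4% of the list. The X chromosome had 0.556 ETS1 and 0.234 ETS2 peaks per Mb. On chromosome 1, 2010 ETS1 peaks (58.4% of that chromosome's) lay in a segment of 1.7 Mb from 132900001 to 134600000, where the ETS2 list had 138. This segment holds 33 protein-coding genes, among them Mdm4, which restrains p53, and Btg2, an antiproliferative gene. Because 6 autosomes (4, 5, 6, 7, 10 and 19) had more ETS2 than ETS1 peaks per Mb, a gene found in 1 list only is given below with its chromosome.

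**Figure D1:**
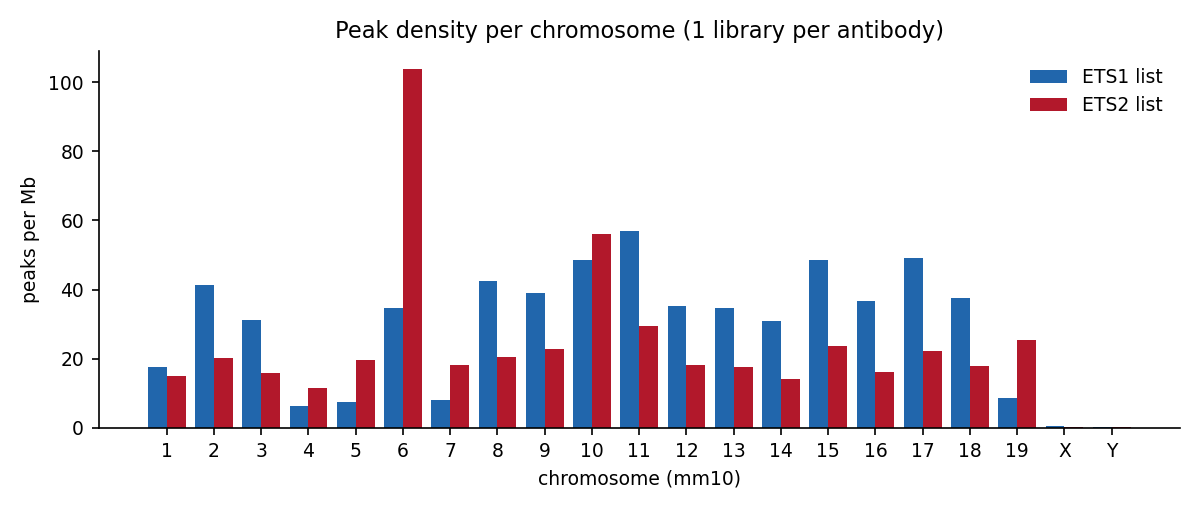
Peaks per Mb (vertical axis) on each mouse chromosome (horizontal axis) for the ETS1 list and the ETS2 list, 1 library each, so the bars carry no error. Among autosomes, ETS2 peaks reached 103.9 per Mb on chromosome 6, and ETS1 peaks fell to 6.44 per Mb on chromosome 4. ETS1 peaks stood at 0.556 per Mb on X and 0.275 on Y.

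**Figure D2:**
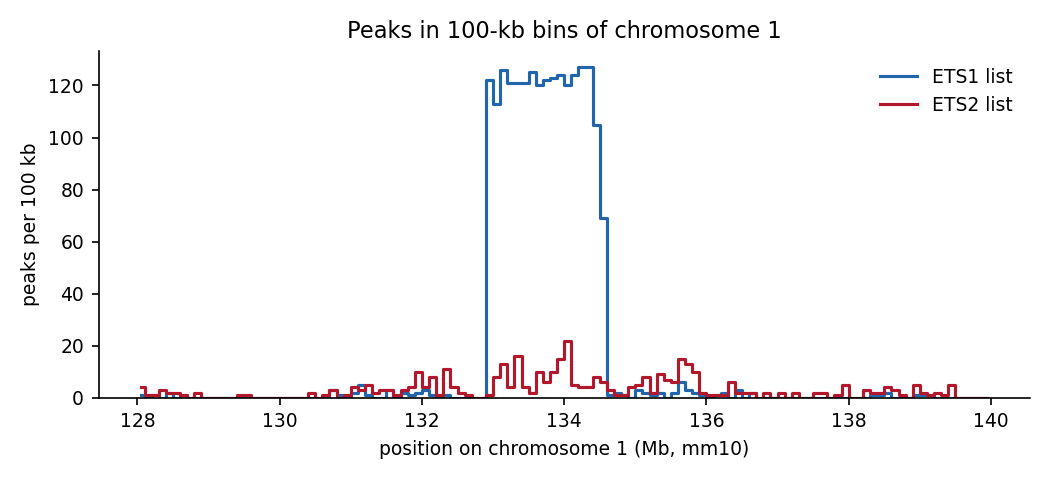
Peaks per 100 kb (vertical axis) along part of chromosome 1 (horizontal axis, Mb) for both lists. The ETS1 line rises to between 69 and 127 peaks per bin across the 1.7 Mb segment that starts at 132900001 and stands at 0 in the bin before it and at 1 in the bin after it.

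The first comparison asked how far both antibodies marked the same sites. Of 77053 ETS1 peaks, 12287 (15.9%, 95% interval 15.7 to 16.2) overlapped an ETS2 peak, and of 63343 ETS2 peaks, 12285 (19.4%, 19.1 to 19.7) overlapped an ETS1 peak. Shared sites included the end of Ets2 itself, where an ETS1 peak (chromosome 16, 95702049 to 95702225) overlapped an ETS2 peak (95702116 to 95702302). They also included one end of Notch1, a receptor of arterial and sprouting endothelium, with peaks at 26503557 to 26503733 and 26503537 to 26503723 on chromosome 2. One end of Vcam1, a leukocyte adhesion molecule, carried peaks at 116129268 to 116129444 and 116129193 to 116129379 on chromosome 3. Random placement of the ETS2 peaks on their own chromosomes gave 790.7 ± 27.9 shared ETS1 peaks (SD over 1000 placements), so the observed number was 15.5-fold higher (permutation test, one-sided, p = 0.001, the smallest these placements can give). The excess held on each of the 19 autosomes, from 9.06-fold to 64.7-fold. Chromosome 4, the autosome with the fewest peaks per Mb in both lists, had 64.7-fold and 26.8% of ETS1 peaks shared. Chromosome 6, densest in ETS2 peaks, had 9.06-fold and 33.1%, so the fold does not rank how much was shared. Genome-wide, the excess was 6.22-fold when the ETS2 peaks were only moved by 5 to 50 kb and 8.39-fold for centres within 500 bp. For the first 50% and the first 10000 peaks of each deposited list it was 29.1-fold and 129-fold. In these last subsets the random number shrank, to 197.8 and 14.1, while the observed share of ETS1 peaks was 15.0% and 18.6%.

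Sharing was commonest at the top of both files, here counted over all 77295 and 63556 deposited peaks, including those on the mitochondrial genome and unplaced contigs. In the first decile of the deposited order 37.3% (36.2 to 38.4) of ETS1 peaks and 47.1% (45.9 to 48.3) of ETS2 peaks were shared, beside 10.1% (9.45 to 10.8) and 12.998% (12.2 to 13.8) in the last decile. Of the first 1000 ETS1 peaks 33.6% were shared and 691 lay in the chromosome 1 segment, whereas 80.1% of the first 1000 ETS2 peaks were shared and 3 lay there. Of the first 100 peaks, 94 ETS1 and 95 ETS2 peaks were shared. Among these first 100, 67% of ETS1 and 7% of ETS2 peaks lay within 1 kb of a gene end. Mitochondrial peaks also stood near the top, with median places at 0.159% and 0.0323% of the order. With no input library analysed, sharing at the top cannot be told apart from places that gather reads under either antibody. The 10 leading peaks of each list were all shared. Those with a nearest protein-coding gene lay at least 29487 bp from an end of it. Places that gather reads were not removed before overlaps were counted.

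**Figure D3:**
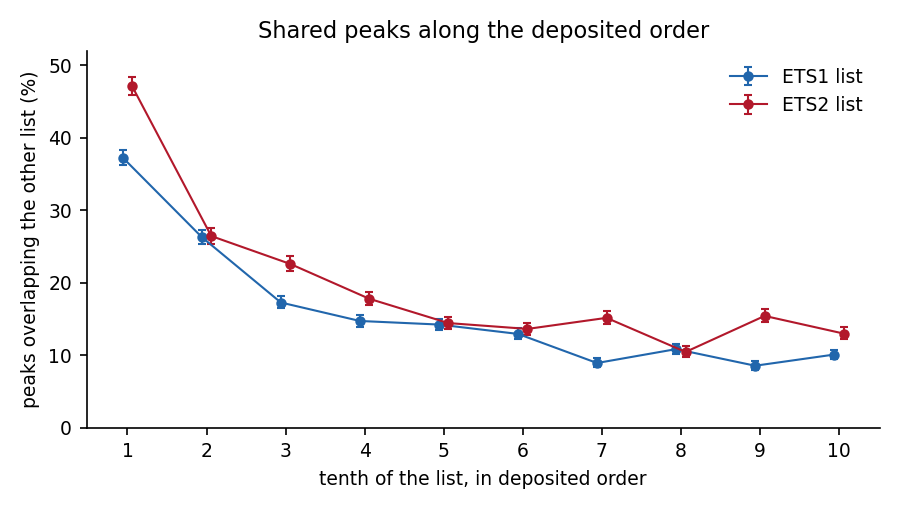
Percent of peaks that overlap a peak of the other list (vertical axis) in each decile of the deposited order (horizontal axis), with 95% Wilson intervals as bars. The share fell from 37.3% to 10.1% in the ETS1 list and from 47.1% to 12.998% in the ETS2 list between the first and the last decile.

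Both lists were concentrated at the ends of genes. Peak centres lay within 1 kb of an annotated gene end for 18.96% (18.7 to 19.2) of ETS1 peaks and 21.9% (21.6 to 22.2) of ETS2 peaks, against 6.30% and 6.36% of random positions, a 3.01-fold (2.97 to 3.06) and a 3.44-fold (3.39 to 3.50) excess. Counting only protein-coding genes, the excess was 4.72-fold and 5.70-fold. The interior of genes held 54.2% of ETS1 and 52.7% of ETS2 peaks, 1.21-fold and 1.15-fold the random share. Intergenic DNA held 26.9% and 25.4%, 0.550 and 0.529 of the random share. Exons, introns and UTRs were not distinguished here.

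Shared sites lay at gene ends more often than sites of one list. Among ETS1 peaks, 38.3% (37.4 to 39.2) of the shared and 15.3% (15.0 to 15.6) of the other peaks were within 1 kb of a gene end (odds ratio 3.44, 3.29 to 3.58, Fisher's exact test). Among ETS2 peaks the shares were 38.3% (37.5 to 39.2) and 17.95% (17.6 to 18.3), with an odds ratio of 2.84 (2.72 to 2.97). Shared peaks also stood earlier in the deposited order, at a median of 30.7% against 53.3% for ETS1 and 33.2% against 53.8% for ETS2. The share at gene ends fell along that order, from 35.8% in the first decile to 13.6% in the last for ETS1. For ETS2 it fell from 39.5% to 16.3%. Shared and other peaks were not matched on their place in the order.

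At the level of genes, 8616 of 21887 protein-coding genes (39.4%) had an ETS1 peak within 1 kb of an end and 8745 (39.96%) an ETS2 peak. Both peaks were found at 6275 genes, against 3442.5 from independent lists, a ratio of 1.82 (odds ratio 11.7, 10.99 to 12.5, Fisher's exact test). Here and below, a gene with both peaks need not carry them at the same end. For Timp2 and Smtn, the nearest ETS1 peak lay at the lower end and the nearest ETS2 peak at the upper end. Allowing for the different share of genes on each chromosome, 3763 were expected. An ETS1 peak alone marked 2341 genes and an ETS2 peak alone 2470, and 10801 genes had neither. A gene said to lack a peak can hold one just outside the 1 kb window or elsewhere over its locus. On the 6 autosomes with more ETS2 than ETS1 peaks per Mb, 390 genes were in the ETS1 list alone and 1364 in the ETS2 list alone. On the other 13 autosomes the numbers were 1931 and 1103. These include chromosome 1, with 71 genes in the ETS1 list alone and 241 in the ETS2 list alone. Outside its dense segment, chromosome 1 had 7.40 ETS1 and 14.4 ETS2 peaks per Mb, so genes there share the limit of the 6 autosomes.

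Of the factors' own genes, Ets2 carried both peaks at its lower-coordinate end on chromosome 16. Ets1 (chromosome 9, 32636241 to 32757820) had an ETS2 peak 266 bp from its upper end (32757993 to 32758179), and its nearest ETS1 peak lay 2814 bp from its lower end. The locus and 10 kb around it held 12 ETS1 and 17 ETS2 peaks. Among 27 genes of the ETS family, 13 (48.1%, 30.7 to 66.0) had an end peak in each list, 8 of them in both, which did not pass the test (adjusted p = 0.546 for each list, Fisher's exact test). Etv3 and Etv5 were among the 8. Erg, which maintains endothelial identity and lies on chromosome 16, had an ETS2 peak 926 bp from its upper end, and an ETS1 peak 1179 bp from it, just outside the window. Fli1 on chromosome 9 had an ETS1 peak 774 bp from its lower end and its nearest ETS2 peak 1687 bp from the upper end. Etv2, an early endothelial specifier on chromosome 7, had neither. That chromosome had 7.91 ETS1 and 18.1 ETS2 peaks per Mb.

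Genes that define endothelial cells were not marked more often than other genes. Of 50 endothelial identity genes, 17 (34%, 22.4 to 47.8) had an ETS1 peak at an end and 18 (36%, 24.1 to 49.9) an ETS2 peak, against 39.4% and 39.96% of other genes (adjusted p = 0.573 and 0.754, Fisher's exact test). Both peaks were present at 6 genes, among them Nrp1, a VEGF co-receptor (chromosome 8, ETS1 peak at 128358712 to 128358888 and ETS2 peak at 128358677 to 128358863), Podxl, a sialomucin, on chromosome 6, and She on chromosome 3. Flt1, which encodes VEGF receptor 1, carried an ETS1 peak 83 bp from its upper end (chromosome 5, 147726433 to 147726609), and the tight junction gene Cldn5 on chromosome 16 was also in the ETS1 list alone. Kdr, which encodes VEGF receptor 2, carried an ETS2 peak 163 bp from its lower end (chromosome 5, 75932571 to 75932757), and Cdh5, encoding VE-cadherin, carried one 557 bp from its upper end (chromosome 8, 104143854 to 104144040). Chromosome 5 had 7.57 ETS1 and 19.6 ETS2 peaks per Mb. Pecam1 had neither peak within 1 kb of an end, although its locus held 11 ETS1 and 3 ETS2 peaks. Tek, the angiopoietin receptor gene, had neither and lies on chromosome 4, with 6.44 ETS1 and 11.4 ETS2 peaks per Mb. Of the identity genes in a single list, 11 were in the ETS1 and 12 in the ETS2 list, of which 2 and 3 lay on the 6 autosomes with more ETS2 peaks per Mb.

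Ligands, receptors and transducers of angiogenesis were marked more often than other genes in both lists. An ETS1 peak lay at an end of 25 of 40 genes (62.5%, 47.03 to 75.8, odds ratio 2.54, adjusted p = 0.0114, Fisher's exact test) and an ETS2 peak at 24 (60%, 44.6 to 73.7, odds ratio 2.23, adjusted p = 0.0347), with 20 genes in both. Vegfa (chromosome 17, 46032817 to 46032993 and 46032689 to 46032875), Vegfc (chromosome 8, 54077783 to 54077959 and 54077809 to 54077995) and Notch1 carried both. Angpt2 on chromosome 8 and Dll4, the Notch ligand of tip cells, on chromosome 2 were in the ETS1 list alone. Ephb4, a venous marker on chromosome 5, and Bmpr2 on chromosome 1 were in the ETS2 list alone, while Vegfb on chromosome 19 and Pgf had neither. The nearest ETS1 peaks lay just outside the window, 1379 bp from an end of Bmpr2, 1199 bp for Vegfb and 1164 bp for Pgf. Against random lists matched on chromosome and gene length the calls ended (permutation test, adjusted p = 0.0588 for ETS1 and 0.114 for ETS2). The ETS2 call also ended in the exact test within 500 bp (odds ratio 1.59, adjusted p = 0.281) and without chromosomes 1 and 6, where 34 genes remained (adjusted p = 0.109). It ended as well without olfactory and vomeronasal receptor genes in the background, where the odds ratio was 1.99 (exact test, adjusted p = 0.0823).

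Matrix and protease genes passed the test in the ETS1 list, with 24 of 41 genes (58.5%, 43.4 to 72.2, odds ratio 2.16, adjusted p = 0.0353, Fisher's exact test), and not in the ETS2 list, with 22 (53.7%, 38.7 to 67.9, odds ratio 1.74, adjusted p = 0.160). The difference between the lists was not tested. Mmp14, a membrane-bound metalloprotease, and the metalloprotease inhibitor genes Timp2 and Timp3 were among 18 genes with both peaks. Mmp14 peaks lay at 54432218 to 54432394 and 54432215 to 54432401 on chromosome 14. Mmp2 and Plat, both on chromosome 8, were in the ETS1 list alone, Mmp10 on chromosome 9 and Lama4 on chromosome 10 in the ETS2 list alone, and Mmp3 and Mmp1a in neither. The ETS1 call ended in the exact test within 2.5 kb (adjusted p = 0.0624), in the permutation test against matched random lists (0.282), without the receptor genes in the background (0.0826) and in the first 50% of the deposited order (0.448), where the ETS2 call appeared (0.0270).

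Genes of endothelial inflammation were at the level of other genes, with an ETS1 peak at 12 of 39 (30.8%, adjusted p = 0.504, Fisher's exact test) and an ETS2 peak at 16 (41.03%, adjusted p = 0.926). The adhesion molecule genes Icam1 and Vcam1 and the macrophage growth factor gene Csf1 were among 9 with both. Nfkb1 on chromosome 3 and Traf1 on chromosome 2 were in the ETS1 list alone. Their nearest ETS2 peaks lay 1231 and 1797 bp from an end. The chemokine genes Cxcl1 and Cxcl10 were in the ETS2 list alone, and both lie on chromosome 5, where ETS1 peaks were sparse. The selectin genes Sele and Selp had no peak of either list over their loci. Both lie on chromosome 1, where ETS1 peaks were sparse outside the dense segment. The nearest peak to an end of Sele lay 45048 bp away.

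Survival and cell cycle genes were marked often. An ETS1 peak lay at 20 of 30 survival and apoptosis genes (66.7%, 48.8 to 80.8, odds ratio 3.01, adjusted p = 0.0128, Fisher's exact test) and an ETS2 peak at 24 (80%, 62.7 to 90.5, odds ratio 5.68, adjusted p = 7.7e-05), including the same 20. Bcl2 (chromosome 1, 106713821 to 106713997 and 106713812 to 106713998), Mcl1 and Bcl2l2, which block apoptosis, had both peaks. Cflar, an inhibitor of death receptor signalling, was in the ETS2 list alone, on chromosome 1, where ETS1 peaks were sparse outside the dense segment. Bcl2l1 had neither peak at an end but 23 ETS1 and 20 ETS2 peaks over its locus. Among 40 cell cycle genes, 26 had an ETS1 peak (65%, 49.5 to 77.9, odds ratio 2.82, adjusted p = 0.00637) and 30 an ETS2 peak (75%, 59.8 to 85.8, odds ratio 4.38, adjusted p = 7.7e-05, exact test), with 22 in both. Ccnd1 (chromosome 7, 144939554 to 144939730 and 144939466 to 144939652), Ccne2 and Cdk1 had both. Ccnd2 and Cdkn1c, the latter on chromosome 7, had neither. The nearest peaks to an end of Ccnd2 lay 1568 bp (ETS1) and 1533 bp (ETS2) away. Ccnd3 on chromosome 17 and Ccna2 on chromosome 3 had the ETS1 peak alone. Their nearest ETS2 peaks lay 1768 and 1262 bp from an end. Ccnb1 on chromosome 13 had the ETS2 peak alone, as did Ccne1 on chromosome 7, which had 7.91 ETS1 and 18.1 ETS2 peaks per Mb. Without chromosomes 1 and 6 the ETS1 call for survival genes ended (exact test, adjusted p = 0.0544). Fewer genes were tested there, 25 in place of 30, of which 16 had both peaks.

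The list of the RAS-ERK pathway and AP-1 was among the most often marked. Of 40 genes of the RAS-ERK pathway and AP-1, 31 had an ETS1 peak (77.5%, 62.5 to 87.7, odds ratio 5.12, adjusted p = 1.47e-05, Fisher's exact test) and 32 an ETS2 peak (80%, 65.2 to 89.5, odds ratio 5.76, adjusted p = 3.46e-06), with 26 in both. The GTPase gene Hras carried both peaks (chromosome 7, 141194258 to 141194434 and 141194196 to 141194382). Nras on chromosome 3 and Spred2 on chromosome 11 were in the ETS1 list alone, and Braf on chromosome 6 and Mapk8 on chromosome 14 in the ETS2 list alone. The nearest ETS2 peak of Spred2 lay 1208 bp from an end. Rras on chromosome 7 and Egr2 had neither. The nearest ETS1 peak lay 1308 bp from an end of Rras. For Egr2 the nearest peaks lay 1600 bp (ETS1) and 1757 bp (ETS2) away. Within 500 bp the ETS1 call ended (exact test, adjusted p = 0.0618).

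Housekeeping genes passed the same test. Of 40 cytosolic ribosomal protein genes, 35 had an ETS1 peak (87.5%, 73.9 to 94.5, odds ratio 9.98, adjusted p = 1.31e-08, Fisher's exact test) and 33 an ETS2 peak (82.5%, 68.0 to 91.3, odds ratio 6.73, adjusted p = 1.35e-06), with 29 in both, such as Rpl3 and Rpl4. Rpl18, on chromosome 7, was the only one of the 40 with neither. Of 40 mitochondrial respiration genes, 28 had an ETS1 peak (70%, odds ratio 3.52, adjusted p = 0.000599) and 28 an ETS2 peak (70%, odds ratio 3.43, adjusted p = 0.000611, exact test), with 21 in both, such as Ndufa5 and Ndufa9. Within 1 kb, the ribosomal protein genes had the highest share of the 17 lists in both peak lists. Within 2.5 kb the RAS-ERK genes stood higher, at 37 of 40 in each list, beside 36 for ETS1 and 34 for ETS2 at ribosomal protein genes.

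Markers of other cell types gave smaller lists of 15 genes each. T lymphocyte genes were marked less often than other genes, with an ETS1 peak at Lck alone, on chromosome 4, and an ETS2 peak at Cd4 alone, on chromosome 6 (6.67% each, 1.19 to 29.8, adjusted p = 0.0197 for each list, Fisher's exact test). Cd3e and Cd3d had neither. The odds ratios were 0.159 for ETS1 and 0.155 for ETS2. The call ended in the exact test within 500 bp for ETS1 (odds ratio 0.234, adjusted p = 0.104) and within 2.5 kb for ETS2 (0.306, adjusted p = 0.0756). It also ended in the first 50% of the deposited order for both (odds ratios 0.252 and 0.253, exact test, adjusted p = 0.157). Without chromosomes 1 and 6, where 11 genes remained, it ended for ETS1 (exact test, adjusted p = 0.119). Smooth muscle genes had a peak at 6 and 7 of 15, with both at Acta2, Tagln and Smtn among others, which encode contractile and actin-associated proteins. Fibroblast genes had a peak at 5 and 6, with both at the collagen genes Col1a1 and Col1a2 and at Twist2. Macrophage genes had a peak at 4 and 3, with both at Cd68, Cd14 and Spi1, and hepatocyte genes at 3 and 4, with both at Apoa1 and Apoa2. Skeletal muscle and heart genes had a peak at 4 and 3, with both at Tnnt3 and Ckm. Neuron genes had an ETS1 peak at 8 and an ETS2 peak at 2 of 15, the latter Tubb3, which is in both lists, and Map2 on chromosome 1. None of these 6 lists passed the exact test (adjusted p from 0.0776 to 1), although the ETS2 list was lower at neuron genes against matched random lists (adjusted p = 0.0455) and without chromosomes 1 and 6 (0.0375), and lower at skeletal muscle and heart genes within 500 bp (0.0147).

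**Figure D4:**
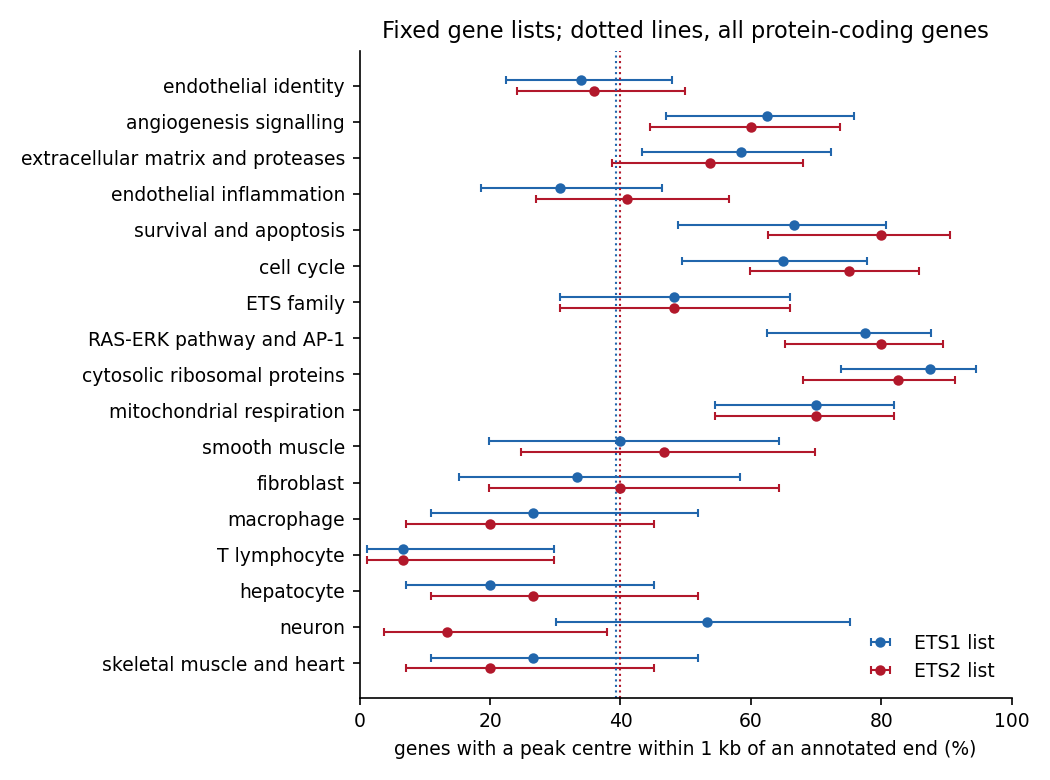
Percent of the genes of each fixed list (vertical axis) that have a peak centre within 1 kb of an annotated end (horizontal axis), for the ETS1 and ETS2 lists, with 95% Wilson intervals as bars and the shares of all protein-coding genes as dotted lines. Cytosolic ribosomal protein genes stood highest, at 87.5% and 82.5%, and T lymphocyte genes lowest in the ETS1 list, at 6.67%.

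Whole loci gave fewer calls than gene ends. Counting peaks over each gene and 10 kb around it, matrix and protease genes had 8.46 ETS2 peaks per gene, 2.41-fold the mean of random lists of the same lengths (adjusted p = 0.0136, permutation test), and survival genes 6.03, 2.35-fold (adjusted p = 0.0391). Hepatocyte genes had 0.667, 0.270 of the random mean (permutation test, adjusted p = 0.0391). In the ETS1 list only the cytosolic ribosomal protein genes passed, with 3.83 peaks per gene, 1.94-fold (permutation test, adjusted p = 0.0136). Endothelial identity genes had 4.48 ETS1 and 4.16 ETS2 peaks per gene, 1.15-fold and 1.34-fold the random mean (permutation test, adjusted p = 0.514 and 0.294). Without chromosomes 1 and 6 the ETS2 value was 2.67 peaks per gene, 0.856 of the random mean. With 50 kb around the gene or in the first 50% of the deposited order none of these 4 calls held, and counting only peaks outside gene ends only the ETS2 call for matrix and protease genes did. With no flank, the ETS2 calls for survival and hepatocyte genes ended (permutation test, adjusted p = 0.051 and 0.319).

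The loci with the most peaks lay mostly in the dense regions of each list. Plekha6 (202 peaks), Atp2b4 (145) and Pik3c2b (97), all in the chromosome 1 segment, led the ETS1 list, followed by Zmiz1 (92) on chromosome 14 and Lpp (88) on chromosome 16. The ETS2 list had 9, 11 and 5 peaks at the first 3 of these. Sox5 (217 peaks), Iqsec1 (164), Foxp1 (148), Exoc4 (129) and Tcf7l1 (125), all on chromosome 6, led the ETS2 list, and the ETS1 list had 38, 25, 62, 37 and 40 peaks there.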

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

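No test was run for these values. They come from peaks outside chromosomes 1 to 19, X and Y, which entered only the shares along the deposited order and the leading peaks. The mitochondrial genome held 13 ETS1 and 12 ETS2 peaks, and unplaced contigs held 229 ETS1 and 201 ETS2 peaks. The limit of 3 that a count of 0 allows is a fixed setting. It is not the number of peaks expected on these sequences. The sources used here include no control library to set beside them.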

How the results depend on the processing

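The alternatives that use the deposited order, leave out chromosomes 1 and 6, match random lists on chromosome, move peaks by 5 to 50 kb, take the expectation within chromosomes or drop receptor genes from the background were chosen after seeing the data. The others were set before the data were examined. The excess of shared peaks kept its direction and side of the threshold in all 8 alternatives run (6.22-fold to 129-fold). The odds ratios of shared peaks at gene ends stayed between 3.12 and 4.23 for ETS1 and between 2.57 and 3.57 for ETS2. The excess at gene ends stayed between 2.26-fold and 4.72-fold for ETS1 and between 2.42-fold and 5.70-fold for ETS2, and the ratio of observed to expected genes in both lists between 1.59 and 2.14. The number of gene lists marked more often at gene ends stayed within 1.5 times of the 7 for ETS1 and the 6 for ETS2. The cause of the changes below was not tested. The number marked less often at gene ends was 1 for each antibody. For ETS1 it was 0 within 500 bp, in the first 50% of the deposited order and without chromosomes 1 and 6. For ETS2 it was 2 within 500 bp, against random lists matched on chromosome and gene length and without chromosomes 1 and 6, and 0 within 2.5 kb and in the first 50% of the deposited order. Over loci, the number of lists higher in ETS1 peaks moved from 1 to 0 with 50 kb, with peaks outside gene ends and in the first 50% of the deposited order, and to 4 without chromosomes 1 and 6. In ETS2 peaks the number of lists higher moved from 2 to 0 with 50 kb and in the first 50% of the deposited order, and to 1 with peaks outside gene ends. The number lower moved from 1 to 0 with 0 kb, 50 kb, peaks outside gene ends and the first 50% of the deposited order.

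No result past its threshold turned direction, while 26 values of lists that had not passed did. At gene ends, the odds ratio within 2.5 kb was 1.27 for ETS1 and 1.09 for ETS2 at endothelial identity genes and 1.23 for ETS1 at skeletal muscle and heart genes, and within 500 bp it was 0.781 for ETS2 at ETS family genes. Against random lists matched on chromosome and gene length it was 0.776 for ETS1 and 0.920 for ETS2 at smooth muscle genes, 0.993 for ETS2 at inflammation genes and 0.645 for ETS2 at fibroblast genes. Without olfactory and vomeronasal receptor genes it was 0.943 for ETS1 at smooth muscle genes, and for ETS2 0.941 at inflammation and 0.917 at fibroblast genes. In the first 50% of the deposited order it was 0.954 for ETS1 and 0.958 for ETS2 at smooth muscle genes, and for ETS2 0.871 at inflammation and 0.958 at fibroblast genes. Over loci, the ratio to random lists in the first 50% of the deposited order was 0.998 at endothelial identity and 0.896 at smooth muscle genes for ETS1. Matched on chromosome it was 0.972 for ETS1 at smooth muscle and 1.03 for ETS2 at inflammation genes. Without chromosomes 1 and 6 it was 1.21 for ETS1 at fibroblast genes, and for ETS2 0.856 at endothelial identity and 0.797 at smooth muscle genes. With 50 kb it was 1.13 for ETS1 at macrophage and 1.03 for ETS2 at T lymphocyte genes. For ETS2 at smooth muscle genes it was 0.806 with 0 kb and 0.944 with peaks outside gene ends.

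Subsets of peaks by score or width, CpG-matched and GC-matched backgrounds and all motif alternatives were not run, because score and width do not vary and no sequence was used. No paired analysis was possible because each antibody had 1 library. The threshold of 30 tags limits what can be seen where reads are few, so a gene without a peak on the X chromosome or on a sparse chromosome is not shown to be unbound.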

Other observations

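The gene families, gene types and the agreement between lists described here, and the tests of read depth on chromosome 6, of a gained segment and of repeats, were chosen only after the results were seen. Beyond the fixed lists, the gene families tested differed widely in how often their ends carried peaks. Among 78 mitochondrial ribosomal protein genes, 55 (70.5%, 59.6 to 79.5) had an ETS1 peak and 57 (73.1%, 62.3 to 81.7) an ETS2 peak, with odds ratios of 3.65 and 4.04 (adjusted p = 1.34e-07 and 1.83e-08, Fisher's exact test, 24 tests of families). Translation initiation factor genes stood at 40 and 42 of 56, proteasome subunit genes at 26 and 25 of 39 and mediator subunit genes at 19 and 20 of 28, and each passed in both lists (adjusted p from 4.61e-07 to 0.00517, exact test). RNA polymerase II subunit genes had an ETS1 peak at 12 of 13 (exact test, adjusted p = 0.000274) and an ETS2 peak at 8 of 13 (adjusted p = 0.169), a difference that was not tested. Histone genes had an ETS1 peak at 19 of 73 (26.03% against 39.4% of other genes, odds ratio 0.550, adjusted p = 0.0331, exact test) and an ETS2 peak at 23 of 73 (31.5% against 39.98%, adjusted p = 0.169), but genes matched on chromosome and length stood at 27.9% and 24.9%, so most of the ETS1 gap went and the ETS2 direction turned. The difference from matched genes was not tested. Serine/arginine splicing factor genes stood at 8 of 11 in each list (exact test, adjusted p = 0.043 and 0.0436), and Zfp zinc-finger genes at 159 and 173 of 367 (adjusted p = 0.142 and 0.00824). Receptor genes of sensory neurons were almost free of peaks. Of 1110 olfactory receptor genes, 27 (2.43%) had an ETS1 peak and 5 (0.450%) an ETS2 peak, against 23.8% and 22.4% of genes matched on chromosome and length, and of 353 vomeronasal receptor genes 2 (0.567%) and 11 (3.12%) did. Keratin genes were low as well, at 12 and 6 of 49 (exact test, adjusted p = 0.0499 and 7.64e-05), while Hox genes stood at 18 of 39 in each list (exact test, adjusted p = 0.432 and 0.513).

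Within 500 bp of an end, tRNA genes carried an ETS1 peak at 99 of 408 (24.3%, 20.4 to 28.7) and an ETS2 peak at 87 (21.3%, 17.6 to 25.6), beside 30.7% and 31.9% of protein-coding genes, 13.9% and 13.5% of lncRNA genes and 3.91% and 2.51% of pseudogenes. The windows at both ends of a short gene, such as a tRNA gene, overlap, so less DNA was searched there. These shares were not matched on gene length. Among genes with a peak of either list at an end, both lists marked 56.6% of all protein-coding genes but 6 of 29 endothelial identity genes (20.7%, 9.85 to 38.4, odds ratio 0.211, adjusted p = 0.00176 over 17 lists, Fisher's exact test). Neuron genes stood lower still, at 1 of 9 (11.1%, odds ratio 0.135, adjusted p = 0.0730, exact test), and survival genes higher, at 20 of 24 (83.3%, odds ratio 3.50, adjusted p = 0.0614, exact test), and neither list passed within 1 kb. For endothelial identity genes the share was 4 of 20 within 500 bp (20% against 48.3% of other genes, adjusted p = 0.108, exact test), 4 of 17 in the first 50% of the deposited order (23.5% against 45.1%, adjusted p = 0.330) and 4 of 25 without chromosomes 1 and 6 (16% against 56.9%, adjusted p = 0.000802). Within 2.5 kb it was 17 of 35 (48.6% against 61.6%, adjusted p = 0.341, exact test), where survival genes (23 of 26, odds ratio 4.21, adjusted p = 0.0339) and RAS-ERK genes (34 of 40, adjusted p = 0.0292) passed with a higher share and T lymphocyte genes (0 of 5, adjusted p = 0.0476) with a lower one. The 10 leading peaks of both lists fell at the same few places, all shared, such as chromosome 2 at 98667043 to 98667219 for ETS1, 1035459 bp from an end of Lrrc4c, and chromosome 9 at 35305356 to 35305532, 29487 bp from an end of Rpusd4. Some stretches were dense in both lists, such as chromosome 13 from 12800001 to 13000000 with 159 ETS1 and 143 ETS2 peaks.

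The ETS2 list held 5.50 times as many peaks per Mb on chromosome 6 as the median of the other autosomes. More binding at the gene ends of that chromosome was argued against, because its excess was 2.495-fold within 1 kb of gene ends and 7.26-fold more than 10 kb away, a ratio of 0.344 (0.272 to 0.428). A difference in read depth along the whole chromosome stays open as a candidate explanation. The ratio of ETS2 to ETS1 peaks was above the median of the other autosomes in each 5 Mb bin of chromosome 6. These were 30 bins, a share of 1, with values from 2.04 to 4.79 beside a median of 0.548 elsewhere. This decides nothing about depth, because chromosome 6 was picked for its ETS2 density and any chromosome-wide cause would give it. Over whole chromosomes the ratio was 2.999 on chromosome 6, 2.956 on chromosome 19 and 2.586 on chromosome 5. Tag counts outside peaks, which could set read depth apart from binding, were not analysed here. The peak lists alone do not separate a chromosome gain from uneven sequencing.

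The ETS1 segment of 1.7 Mb on chromosome 1 had 1182 peaks per Mb beside 7.40 on the rest of the chromosome. Binding at its genes was argued against, since the share of its peaks within 1 kb of a gene end was 1.07 times (0.958 to 1.19) that of all positions there. Reads shared between repeats were argued against by the ETS2 list, which held 0.069 (0.0574 to 0.0816) times as many peaks there, although its own density of 81.2 peaks per Mb exceeded the 14.4 on the rest of chromosome 1. A gain of one DNA segment in the ETS1 library stays open as a hypothesis. A share of 1 of its 100 kb bins exceeded the 99th percentile of other bins of chromosome 1, which was 6 peaks, but this decides nothing, because the segment was defined by bins of at least 50 peaks. No biological explanation beyond binding at genes was tested.

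Genes in a single list differed in number by chromosome. If read depth along chromosomes were the cause, autosomes with more ETS2-only than ETS1-only genes should be those with more ETS2 than ETS1 peaks over 10 kb from gene ends, and 18 of 19 autosomes were on the matching side (Fisher's exact test, two-sided, p = 0.000258). The exception was chromosome 1, which carries the dense ETS1 segment. Both counts come from the same peak lists, so any chromosome-wide difference in peak number would give this match. It does not single out depth. Depth under a common tag threshold remains a candidate explanation for part of the single-list genes, and a true preference of ETS1 or ETS2 for some genes stays open and untested.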
